A study of Arabidopsis thaliana with 15 samples.

How the data were processed

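Gene expression was measured on arrays in hypocotyls of the Arabidopsis thaliana ecotype Col-0. The plants grew in short days for 6 weeks and were then moved to long days, which induces flowering. Hypocotyls were taken 0, 1, 2, 4 and 10 days after the switch. Each day has 3 replicates and each replicate is a pool of 8 plants, so there are 15 arrays. The labels give no hour of harvest and no processing batch. Day 0 is the only reference that they give.

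The deposited values are normalised array intensity, 1 column per array. RMA and Partek are named in the submitters' processing notes, and their versions, their roles, the background correction and the annotation version are not given in the sources used here. The deposited intensity values are positive and linear with nearly equal distributions in all arrays, so they were taken to log2 with no pseudocount and no further scaling. Array medians ran from 84.1 to 90.6 on the intensity scale. The table holds 38408 probe sets. Of these, 16722 are annotated to exactly 1 gene, 759 to several genes and 20927 to none. Control probe sets are not marked, so all 38408 were tested. Of the probe sets with 1 gene, 16574 matched the reference gene table by gene identifier. All 16722 probe sets with 1 gene cover 16548 different genes, of which 1805 have a symbol other than a locus tag. The build behind the array annotation is not given in the sources used here, so no genome positions are printed.

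The values were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per day over all 15 arrays, which leaves 10 residual degrees of freedom and gives all days 1 shared estimate of the spread. The moderated F test asked which probe sets changed over the 5 days. Contrasts compared days 1, 2, 4 and 10 with day 0, and day 2 with day 1, day 4 with day 2 and day 10 with day 4. The tests are two-sided, p-values were adjusted by the Benjamini-Hochberg method over all probe sets, and a probe set was called at an adjusted p below 0.05. Folds are ratios of geometric means of 3 pools against 3 pools. Standard errors (SE) are on the log2 scale and come from the moderated fit. Since the replicates are pools of separate plants, the p-values measure the spread between pools, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

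Gene lists for the tissue and the treatment were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives. The rule names the 8 largest rises and the 8 largest falls of each comparison among called probe sets with exactly 1 gene whose 3 pools of one day all lie on the same side of the 3 pools of the other. It adds up to 5 members of each list by smallest adjusted p, and 23 genes always named. Where several probe sets measure a gene, that with the highest mean over all arrays was used. The 25 lists hold 470 members by symbol, of which 52 could be matched by locus tag to a probe set with 1 gene. Of the lists, 9 have at least 3 such members and were tested. They are, with matched and all members, xylan synthesis (4 of 22), lignin synthesis and polymerisation (5 of 24), cambium (4 of 28), cell division and DNA replication (3 of 31), ABA-responsive genes (7 of 27), gibberellin synthesis and signalling (3 of 28), auxin response and transport (4 of 23), floral transition (5 of 25), and circadian clock and photoperiod (3 of 27). Each list result covers only the matched part of its list. A further 9 lists have 1 or 2 matched members, whose values are given singly. The other 7 lists have 0 named members and were not analysed here. They are secondary wall regulators, secondary wall cellulose, xylem cell death, abscisic acid (ABA) receptors and signalling, periderm and suberin, salicylic acid defence, and heat shock. None of the 23 genes always named was matched by locus tag, and these are not analysed here either. They include NST1, VND6 and MYB46, the secondary wall cellulose genes CESA4, CESA7 and CESA8, and the ABA synthesis genes ABA1 and NCED3. The ABA-responsive genes RD29B and RAB18, and FT, SOC1, GA20OX1, WOX4 and PXY, are also among them.

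Lists were tested with camera from limma, which asks whether the members of a list rank higher or lower than the other genes, on 1 probe set per gene with a preset inter-gene correlation of 0.01. Adjustment was over the lists within each comparison. Members past the test were counted over all probe sets and over the list alone. Other lists were added after the data were seen: cell division, nuclear photosynthesis, starch, monolignol glucosides, ER body, anthocyanin, CC-type glutaredoxins and plastid-encoded genes, along with families of 5 or more genes that share a symbol stem. Some of their members were among the genes with the largest changes, so these lists are no independent evidence of direction. A list of mitochondrion-encoded genes had 0 members.

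The alternatives were centring each array on its median, cyclic loess between arrays, the lowest 25% of probe sets by mean left out, 1 probe set per gene, the trended and robust fit, array weights, only the 6 arrays of the days compared, the replicate number as a block, an F test without moderation, an estimated inter-gene correlation, the self-contained test fry, and leaving out each of the 15 pools in turn. In addition, the arrays were split into other groups of the same sizes, 100 drawn splits for the F test and all 10 splits for each pair of days. The procedure was tested on simulated data with the size and spread of these arrays. Of 38408 probe sets 200 were changed on day 1, and the noise of each probe set was drawn independently. For day 1 against day 0 it called 19.4% of the 67 probe sets changed by 0.5 on the log2 scale, 76.1% of the 67 changed by 1 and 98.5% of the 66 changed by 2. It also called 9 unchanged probe sets. The list test called the raised list and none of the others. With independent noise this cannot show how the list test does on members that vary together.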

Results

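The data are intensities of 38408 probe sets on 15 arrays of Col-0 hypocotyls, with 3 pools of 8 plants for each of days 0, 1, 2, 4 and 10 after the move from short to long days. The series concerns xylem fibre differentiation and abscisic acid (ABA), and the time course asks which transcripts of the hypocotyl change after flowering is induced. Arrays of the same day correlated at r = 0.983 to 0.990 and arrays of different days at 0.965 to 0.988, both across probe sets, which are not independent replicates. The median residual SD between pools of a day was 0.18 on the log2 scale. All folds below rest on n = 3 pools per day, and each ± value is the SE of the log2 difference.

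Over the whole course, genes of several groups moved in different directions. On day 10 the xylan genes IRX10 and IRX15 stood 3.33-fold and 3.23-fold above day 0, while the ABA-responsive gene COR15A stood 10.2-fold below it and the anthocyanin gene UF3GT 17.8-fold below it. GI, a clock and photoperiod gene, was lowest on day 1, 3.48-fold below day 0. GH3.3, an auxin-responsive gene, was 4.29-fold above day 0 on day 2 and not detectably different from it on day 10. The moderated F test called 15936 of 38408 probe sets (41.5%) as changed over the 5 days. The first principal component held 28.8% of the variance and the second 17.5%, and on this plane days 0 and 1 lay closest to each other.

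**Figure D1:**
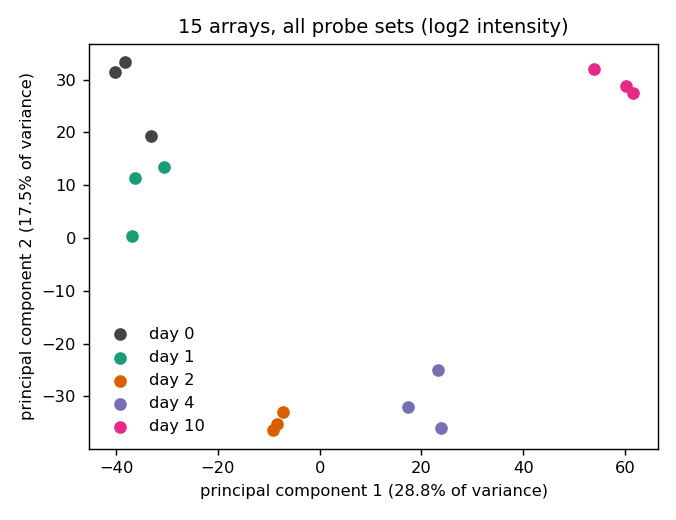
Each point is 1 of the 15 arrays, placed by its scores on principal component 1 (28.8% of the variance, x axis) and principal component 2 (17.5%, y axis) of all log2 intensities, and colours mark the day. Days 0 and 1 lie at −40.3 to −30.7 on the x axis and day 10 at 53.9 to 61.5, with days 2 and 4 between them and lowest on the y axis.

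**Figure D2:**
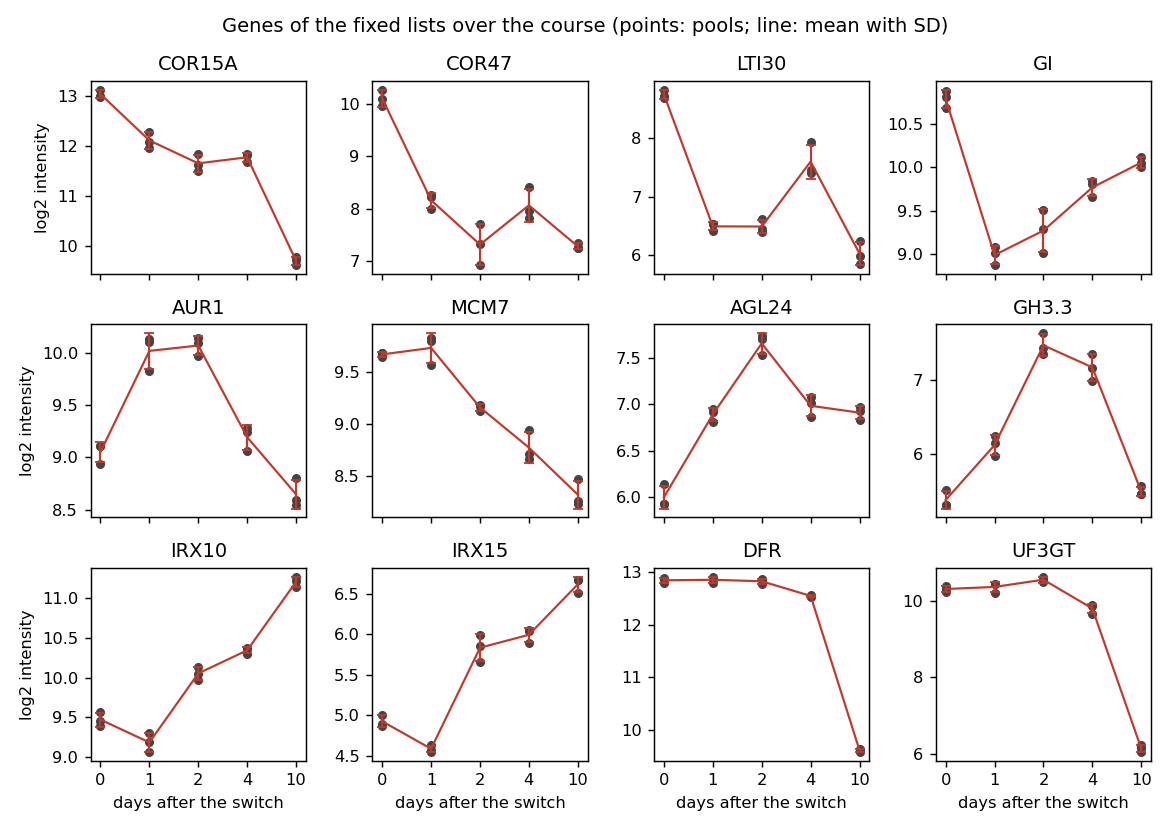
Log2 intensity (y axis) of 12 genes on days 0, 1, 2, 4 and 10 after the switch (x axis, days evenly spaced), where points are pools and the line joins the means of 3 pools with their SD, and the y ranges differ between panels and do not start at 0. IRX10 goes from 9.47 on day 0 to 11.2 on day 10, and COR15A falls 10.2-fold over the same span.

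Day 1 against day 0 asks what differs 1 day after the switch. Some ABA-responsive genes fell: LTI30 (AT3G50970), a dehydrin, was 4.82-fold lower (log2 −2.27 ± 0.14, adjusted p = 3.76e-06), COR47 (AT1G20440), another dehydrin, 3.87-fold lower (−1.95 ± 0.19, adjusted p = 7.83e-05) and COR15A (AT2G42540), a chloroplast protein of cold and drought responses, 1.90-fold lower (−0.93 ± 0.10, adjusted p = 2.10e-04). Its relative COR15B (AT2G42530) was 4.33-fold lower (−2.12 ± 0.10, adjusted p = 7.96e-07). Of the 3 clock genes 2 fell too, with GI (AT1G22770) 3.48-fold lower (−1.80 ± 0.11, adjusted p = 4.21e-06) and RVE6 (AT5G52660), a MYB-like clock activator, 1.35-fold lower (−0.44 ± 0.08, adjusted p = 0.00410). The mitotic Aurora kinases AUR1 (AT4G32830) and AUR2 (AT2G25880) rose 1.95-fold (0.96 ± 0.11, adjusted p = 1.77e-04) and 1.92-fold (0.94 ± 0.10, adjusted p = 1.99e-04). AGL24 (AT4G24540), a MADS-box promoter of flowering, rose 1.86-fold (0.90 ± 0.09, adjusted p = 8.44e-05).

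Of the 7 ABA-responsive genes matched by locus tag, out of 27 in the list, 4 fell and 0 rose on day 1, or 5 and 0 adjusted over the list alone. These 7 as a list lay below the other genes (median log2 −0.53, adjusted p = 1.87e-07). The other matched members were KIN1 (log2 −0.53), ABR (−0.10) and HIS1-3 (−0.02), which did not pass, and COR6.6 (−0.31 ± 0.08, adjusted p = 0.0417). The call of COR6.6 was lost at 0.0828 with the replicate number as a block, and at up to 0.144 when a pool was left out. RD29A, RD29B and RAB18 are among the ABA-responsive genes of the list that were not matched, so the result does not cover them. Of the 3 clock genes, 2 fell, also over the list alone (median −0.44, adjusted p = 9.09e-05), and CDF5 was at −0.14. Of the 3 cell division genes, AUR1 and AUR2 rose (median 0.94, adjusted p = 4.44e-04) and MCM7, a replication helicase subunit, was at 0.06, with the same 2 adjusted over the list alone. These 3 lists held with an estimated correlation, but at a larger adjusted p of 0.00991 each. Among 4 auxin genes GH3.3 (AT2G23170), which conjugates auxin to amino acids, rose 1.68-fold (0.74 ± 0.11, adjusted p = 0.00150), and the list passed (median 0.26, adjusted p = 0.0194). Its call was lost at adjusted p = 0.0652 with an estimated correlation. The floral list passed as well, with AGL24 as the 1 riser of 5 members (median 0.17, adjusted p = 0.0194), and its call was lost at adjusted p = 0.0652 with an estimated correlation and at 0.0579 without day 1 replicate 3. In both lists the count adjusted over the list alone was again 1. The xylan, lignin and cambium lists did not pass (adjusted p = 0.410 to 0.525). Of 4 xylan genes IRX15L (AT5G67210) rose 1.21-fold (0.27 ± 0.07, adjusted p = 0.0346) and IRX15 (AT3G50220) fell 1.26-fold (−0.34 ± 0.09, adjusted p = 0.0494), and 2 fell adjusted over the list alone. Both calls were lost with the replicate number as a block, at 0.0646 and 0.0818, and when a pool was left out, at up to 0.128 and 0.156. In the lignin list the median was 0.05 and the mean −0.08, and the peroxidase PRX72 (AT5G66390) fell 1.52-fold (−0.61 ± 0.10, adjusted p = 0.00403). In the cambium list PHV (AT1G30490), an HD-ZIP III regulator of vascular patterning, rose 1.23-fold (0.30 ± 0.06, adjusted p = 0.00611). No member of the gibberellin list, the receptors GID1A, GID1B and GID1C, passed over all probe sets, and 2 fell adjusted over the list alone. The gibberellin list did not pass (median −0.17, adjusted p = 0.0602), but passed without day 1 replicate 1, day 2 replicate 3 or day 10 replicate 2, at an adjusted p of 0.0395 to 0.0464.

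The largest named rises on day 1 were AT1G08440, of the aluminium-activated malate transporter family, at 5.08-fold (2.35 ± 0.25, adjusted p = 1.62e-04), AT3G50610 at 3.93-fold, AT5G66816 at 3.34-fold, AT3G46280 at 3.13-fold, AT4G08869 at 3.08-fold and the glycosyl hydrolase family 9 gene GH9A3 (AT4G24260) at 3.06-fold (1.61 ± 0.14, adjusted p = 4.32e-05). AT4G08869 passed at adjusted p = 0.0393, a call lost at 0.0556 with the replicate number as a block and at up to 0.116 when a pool was left out. The largest named fall was AT3G15450 at 8.96-fold (−3.16 ± 0.18, adjusted p = 3.35e-06), ahead of the CC-type glutaredoxin AT3G62950 at 5.2-fold, and AT4G16008 and AT5G59080 fell 4.48-fold and 4.44-fold. The test called 1874 of 38408 probe sets (4.88%), 919 higher and 955 lower, of which 70 and 167 changed at least 2-fold. Without day 0 replicate 2 the count was 1190, and with only the 6 arrays of the days compared it was 917, where AT3G62950, AT4G08869, COR6.6, IRX15, IRX15L, RVE6, PRX72 and PHV did not pass. The shares of higher and lower calls depended on the scaling, with 1145 higher and 773 lower after median centring and 957 and 945 with cyclic loess.

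Day 2 against day 0 asks the same 1 day later, and here 3 of the 4 xylan genes rose. IRX15 rose 1.88-fold (log2 0.91 ± 0.09, adjusted p = 2.96e-05), IRX15L 1.79-fold (0.84 ± 0.07, adjusted p = 6.77e-06) and IRX10 (AT1G27440) 1.5-fold (0.58 ± 0.08, adjusted p = 2.57e-04). All take part in making the xylan of secondary walls. GH3.3 rose 4.29-fold (2.1 ± 0.11, adjusted p = 3.11e-07) and AGL24 rose 3.17-fold (1.67 ± 0.09, adjusted p = 3.11e-07). COR47 was 6.96-fold lower (−2.80 ± 0.19, adjusted p = 1.80e-06), LTI30 4.83-fold lower (−2.27 ± 0.14, adjusted p = 8.36e-07) and GI 2.86-fold lower (−1.52 ± 0.11, adjusted p = 3.78e-06).

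On day 2, 3 of the 4 xylan genes rose, and all 4 adjusted over the list alone (median log2 0.71, adjusted p = 1.46e-04). The fourth, IRX10L, was at 0.20. Of the 7 ABA-responsive genes 4 fell and 1 rose, the same adjusted over the list alone (median −0.58, adjusted p = 1.46e-04). The riser was HIS1-3 (AT2G18050), a drought-inducible linker histone, at log2 0.99 ± 0.27 (adjusted p = 0.0236), and its call was lost, at an adjusted p of up to 0.0884, without day 0 replicate 1 or 3 or day 2 replicate 2 or 3. Of the 3 clock genes 2 fell, and all 3 adjusted over the list alone (median −0.89, adjusted p = 2.94e-04), with RVE6 1.85-fold lower (−0.89 ± 0.08, adjusted p = 1.03e-05). Of the 4 auxin genes 2 rose, and 3 adjusted over the list alone (median 0.57, adjusted p = 0.00292), with GH3.5 (AT4G27260), which also conjugates auxin, up 1.47-fold (0.55 ± 0.11, adjusted p = 0.00401). All of these 4 lists held with an estimated correlation, at adjusted p = 0.0126 for xylan and clock and 0.0342 for ABA-responsive and auxin genes. Cell division genes moved in both directions, with AUR1 up 2.02-fold (1.02 ± 0.11, adjusted p = 4.47e-05), AUR2 up 1.65-fold and MCM7 (AT4G02060) down 1.42-fold (−0.51 ± 0.10, adjusted p = 0.00247), and the list did not pass (adjusted p = 0.191). The floral list did not pass either (adjusted p = 0.0546), but passed with cyclic loess at 0.0399 and without day 0 replicate 2, day 2 replicate 1 or day 10 replicate 3 at 0.0192 to 0.0497. Nor did the lignin, cambium and gibberellin lists pass (adjusted p = 0.680 to 0.901). Median and mean differed in sign for cambium (−0.02 and 0.04) and for lignin (0.08 and −0.02). PHV rose 1.29-fold (0.36 ± 0.06, adjusted p = 6.78e-04), HCT (AT5G48930), an enzyme of monolignol synthesis, rose 1.24-fold (0.31 ± 0.07, adjusted p = 0.00887) and PRX72 fell 1.52-fold (−0.60 ± 0.10, adjusted p = 0.00152).

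AT1G08440 had the largest named rise on day 2 at 11.2-fold (3.48 ± 0.25, adjusted p = 3.23e-06), followed by AT5G66816 at 10.3-fold (3.37 ± 0.12, adjusted p = 2.17e-08). The CC-type glutaredoxin AT4G33040 rose 4.50-fold (2.17 ± 0.11, adjusted p = 2.98e-07). AT3G15450 fell 12.7-fold (−3.66 ± 0.18, adjusted p = 2.98e-07), AT5G59080 fell 10.6-fold (−3.41 ± 0.16, adjusted p = 2.60e-07) and AT1G56300, a DnaJ-domain chaperone gene, fell 8.05-fold (−3.01 ± 0.07, adjusted p = 5.89e-10). In total 7832 probe sets (20.4%) were called, 3859 higher and 3973 lower, of which 277 and 683 changed at least 2-fold. With only the 6 arrays compared the count was 5021 and HCT did not pass. After median centring 5236 were higher and 3084 lower, and with cyclic loess 4060 and 3907.

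Day 4 against day 0 covers the middle of the course, where the xylan genes were above day 0 and the ABA-responsive genes split. IRX15 rose 2.1-fold (log2 1.07 ± 0.09, adjusted p = 5.22e-06), IRX15L 1.86-fold (0.90 ± 0.07, adjusted p = 2.33e-06), IRX10 1.83-fold (0.87 ± 0.08, adjusted p = 8.26e-06) and IRX10L (AT5G61840) 1.25-fold (0.32 ± 0.07, adjusted p = 0.00450). COR47 was 4.14-fold lower (−2.05 ± 0.19, adjusted p = 1.17e-05), COR15A 2.41-fold lower (−1.27 ± 0.10, adjusted p = 4.97e-06) and LTI30 2.23-fold lower (−1.16 ± 0.14, adjusted p = 7.74e-05). HIS1-3 rose 4.34-fold (2.12 ± 0.27, adjusted p = 1.49e-04). The flowering genes AGL24 and AGL42 (AT5G62165), a MADS-box gene related to SOC1, rose 1.99-fold (0.99 ± 0.09, adjusted p = 8.48e-06) and 1.64-fold (0.71 ± 0.14, adjusted p = 0.00256).

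All 4 xylan genes rose on day 4, over all probe sets and adjusted over the list alone (median log2 0.88, adjusted p = 6.22e-05). The xylan list held with an estimated correlation, at adjusted p = 0.00931. Of the 7 ABA-responsive genes 4 fell and 1 rose by both counts, with COR6.6 (−0.29) lost at adjusted p = 0.0528 without day 0 replicate 2 and at 0.0532 without day 4 replicate 1. The list did not pass (median −0.29, adjusted p = 0.0778), although it passed after median centring at 0.0444 and without day 0 replicate 3 or day 4 replicate 1 at 0.0386 and 0.0365. Its highest adjusted p was 0.303, with an estimated correlation. The test fry, which does not compare a list with other genes, gave 2.13e-04. Of 4 auxin genes 2 rose by both counts, GH3.3 at 3.48-fold (1.80 ± 0.11, adjusted p = 5.58e-07) and GH3.5 at 1.38-fold (0.47 ± 0.11, adjusted p = 0.00854). The auxin list passed at adjusted p = 0.0491 (median 0.42), a call lost at adjusted p = 0.116 with an estimated correlation. Of 3 clock genes 2 fell by both counts, GI 2.03-fold (−1.02 ± 0.11, adjusted p = 4.42e-05) and RVE6 1.37-fold (−0.45 ± 0.08, adjusted p = 8.85e-04). The clock list passed at adjusted p = 0.0491 (median −0.45), a call lost at adjusted p = 0.116 with an estimated correlation and at 0.0621 with the replicate number as a block. Without a pool the adjusted p of the clock list ran from 0.0339 to 0.0855, and that of the auxin list from 0.016 to 0.0855. With fry, which does not compare a list with other genes, they were 1.42e-05 and 1.36e-05. MCM7 fell 1.86-fold (−0.90 ± 0.10, adjusted p = 3.33e-05), AUR1 and AUR2 were at 0.14 and 0.14, and the cell division list did not pass (adjusted p = 0.635, median 0.14, mean −0.21). The floral list did not pass (adjusted p = 0.117), and neither did cambium, gibberellin and lignin (adjusted p = 0.635 to 0.744). PRX72 fell 1.90-fold (−0.93 ± 0.10, adjusted p = 5.06e-05), while HCT and PHV rose 1.23-fold each.

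The largest named rises on day 4 were AT1G80130 at 12.5-fold (3.64 ± 0.24, adjusted p = 1.14e-06), AT1G08440 at 10.6-fold, AT5G66816 at 10.3-fold and AT1G22480, a cupredoxin family gene, at 9.63-fold (3.27 ± 0.21, adjusted p = 8.84e-07). AT5G44973 fell 14.5-fold (−3.86 ± 0.18, adjusted p = 8.81e-08), AT4G12490, of the lipid transfer protein superfamily, fell 12.5-fold (−3.65 ± 0.20, adjusted p = 2.77e-07), and the CC-type glutaredoxins AT1G03020, AT4G15660 and AT4G15700 fell 10.7-fold, 10.3-fold and 9.06-fold. The test called 9869 probe sets (25.7%), 4424 higher and 5445 lower, of which 493 and 731 changed at least 2-fold. After median centring 6134 were higher and 3989 lower, with cyclic loess 5014 and 4897, and with only the 6 arrays compared GH3.5 and HCT did not pass. The number of lists past the test, 3, went to 1 without any of 8 pools, namely day 0 replicate 2, day 1 replicates 2 and 3, day 2 replicate 2, day 4 replicate 3 and day 10 replicates 1, 2 and 3.

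Day 10 against day 0 spans the whole course. IRX10 rose 3.33-fold (log2 1.73 ± 0.08, adjusted p = 1.23e-08) and IRX15 rose 3.23-fold (1.69 ± 0.09, adjusted p = 4.62e-08). COR15A fell 10.2-fold (−3.34 ± 0.10, adjusted p = 7.28e-10), COR47 fell 7.13-fold (−2.83 ± 0.19, adjusted p = 3.67e-07), LTI30 fell 6.67-fold (−2.74 ± 0.14, adjusted p = 3.13e-08) and KIN1 (AT5G15960), a cold- and ABA-inducible gene, fell 5.79-fold (−2.53 ± 0.19, adjusted p = 1.20e-06). HIS1-3 rose 4.98-fold (2.32 ± 0.27, adjusted p = 4.44e-05). The anthocyanin genes UF3GT (AT5G54060), a glycosyltransferase, and DFR (AT5G42800), dihydroflavonol reductase, fell 17.8-fold (−4.16 ± 0.09, adjusted p = 4.61e-11) and 9.38-fold (−3.23 ± 0.06, adjusted p = 1.26e-11). The green-tissue genes RCA and LHCB4.1 fell 2.33-fold and 1.63-fold over the same span. Among floral genes AGL42 rose 2.62-fold (1.39 ± 0.14, adjusted p = 1.18e-05), AGL24 1.89-fold (0.92 ± 0.09, adjusted p = 7.89e-06) and FD (AT4G35900), the bZIP partner of the florigen FT, 1.88-fold (0.91 ± 0.10, adjusted p = 1.92e-05).

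By both counts, over all probe sets and adjusted over the list alone, 4 of 4 xylan genes rose on day 10 (median log2 1.23, adjusted p = 5.21e-05). Also by both counts, 6 of 7 ABA-responsive genes fell and 1, HIS1-3, rose (median −2.53, adjusted p = 4.98e-05). Likewise 3 of 3 cell division genes fell (median −0.54, adjusted p = 0.00582). These 3 lists held with an estimated correlation, at adjusted p = 0.0111, 0.032 and 0.032. The ABA-responsive genes that fell are COR15A, COR47, LTI30, KIN1, COR6.6 and ABR. RD29A, RD29B and RAB18 of that list were not matched, so the result covers only part of it. MCM7 fell 2.55-fold (−1.35 ± 0.10, adjusted p = 5.94e-07), AUR2 1.45-fold (−0.54 ± 0.10, adjusted p = 0.00182) and AUR1 1.32-fold (−0.41 ± 0.11, adjusted p = 0.0112). The clock list did not pass (adjusted p = 0.733), and its median was −0.41 and its mean 0.15. Its members went both ways, with GI 1.66-fold lower (−0.73 ± 0.11, adjusted p = 3.23e-04), RVE6 1.33-fold lower and CDF5 (AT1G69570), a Dof factor that delays flowering, 3.04-fold higher (1.60 ± 0.14, adjusted p = 4.49e-06). Of 5 floral genes 3 rose and 1 fell, and the list did not pass (adjusted p = 0.139) but did so at 0.0286 without dim genes. The 1 that fell was SNZ (AT2G39250), an AP2-like repressor of flowering, at 1.44-fold (−0.52 ± 0.14, adjusted p = 0.0108), and its adjusted p was 0.0506 without day 0 replicate 2 and 0.00604 to 0.0506 over its alternatives. Auxin, gibberellin, cambium and lignin genes as lists did not pass (adjusted p = 0.733 to 0.978), and GH3.3 was at log2 0.12 ± 0.11. In the cambium list PHV rose 1.27-fold, and the genes of the secreted peptides CLE41 (AT3G24770) and CLE44 (AT4G13195), which keep the cambium dividing, fell 1.33-fold (−0.42 ± 0.09, adjusted p = 0.00346) and 1.31-fold (−0.39 ± 0.08, adjusted p = 0.00361). In the lignin list HCT rose 1.37-fold (0.45 ± 0.07, adjusted p = 4.17e-04) and PRX72 fell 1.49-fold.

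The largest named rises on day 10 were AT1G22480 at 29.2-fold (4.87 ± 0.21, adjusted p = 1.07e-08), AT4G12290, a copper amine oxidase gene, at 19.96-fold (4.32 ± 0.19, adjusted p = 1.29e-08) and AT2G31930 at 16.8-fold. GH9B5 (AT1G19940), of glycosyl hydrolase family 9, rose 7.77-fold (2.96 ± 0.17, adjusted p = 1.00e-07). AT4G11190, of the dirigent family, fell 50.2-fold (−5.65 ± 0.14, adjusted p = 9.28e-11), AT4G12490 fell 26.7-fold and AT1G03020 fell 18.9-fold. The test called 11066 probe sets (28.8%), 5672 higher and 5394 lower, of which 774 and 1063 changed at least 2-fold. After median centring 6426 were higher and 4813 lower, while cyclic loess turned the balance to 5488 and 5623.

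**Figure D3:**
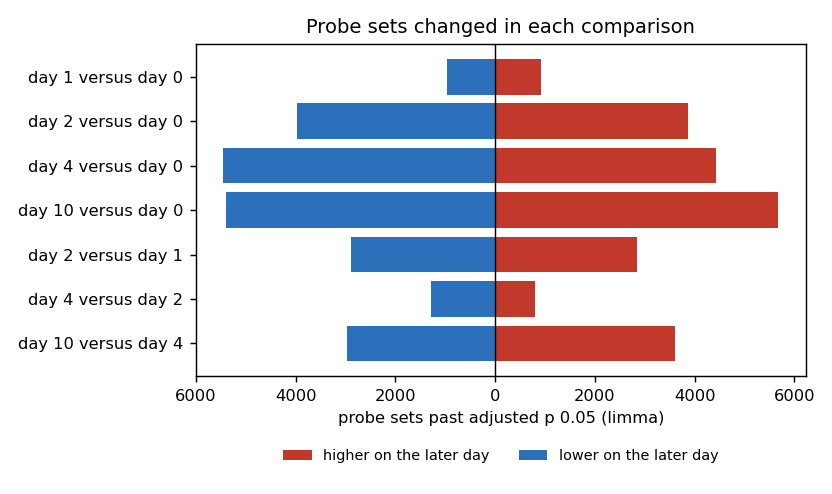
Bars show the number of probe sets past an adjusted p of 0.05 in limma (x axis, starting at 0 in both directions) for each of the 7 comparisons (y axis), red to the right for higher and blue to the left for lower on the later day. The bars are shortest for day 1 against day 0 (919 and 955) and day 4 against day 2 (795 and 1285), and longest for day 10 against day 0 (5672 and 5394).

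The steps between neighbouring days show when the changes took place. From day 1 to day 2 the same 3 xylan genes rose, IRX15 by 2.38-fold from its lower day 1 level (log2 1.25 ± 0.09, adjusted p = 4.39e-05), IRX10 by 1.83-fold (0.87 ± 0.08, adjusted p = 9.94e-05) and IRX15L by 1.48-fold (0.56 ± 0.07, adjusted p = 3.16e-04). GH3.3 rose 2.56-fold (1.36 ± 0.11, adjusted p = 7.96e-05) and AGL24 rose 1.70-fold (0.77 ± 0.09, adjusted p = 2.63e-04). MCM7 fell 1.49-fold (−0.57 ± 0.10, adjusted p = 0.00203), RVE6 1.37-fold (−0.45 ± 0.08, adjusted p = 0.00203) and COR47 1.80-fold (−0.85 ± 0.19, adjusted p = 0.0101). Of 4 xylan genes 3 rose, and 4 adjusted over the list alone (median 0.72, adjusted p = 5.22e-06), which held with an estimated correlation at 0.00434. Of 4 auxin genes 1 rose, and 2 adjusted over the list alone (median 0.31, adjusted p = 0.0487). The auxin call was lost at adjusted p = 0.167 with an estimated correlation and at 0.0607 after median centring. Without a pool the adjusted p of this list ran from 0.0316 to 0.15. The test fry, which does not compare a list with other genes, gave 1.85e-04. The other 7 lists did not pass (adjusted p = 0.277 to 0.978). Of 7 ABA-responsive genes 3 fell and 1 rose, and the calls of COR6.6 (−0.27) and the riser HIS1-3 (1.00) were lost with the block, at 0.0605 and 0.0514, and without a pool, at up to 0.130 and 0.107. The largest named rise was AT2G37870 at 4.92-fold (2.3 ± 0.70, adjusted p = 0.0449), a call lost at up to 0.123 when a pool was left out, and its log2 value was 1.21 without day 1 replicate 2. The glutaredoxin AT4G33040 rose 3.93-fold (1.97 ± 0.11, adjusted p = 1.60e-05), and SWEET4 (AT3G28007), a sugar transporter, and RALFL32 (AT4G14010), a secreted signalling peptide, rose 2.86-fold (1.52 ± 0.23, adjusted p = 0.00116) and 2.85-fold. AT2G38430 fell 3.19-fold (−1.67 ± 0.20, adjusted p = 3.30e-04). In all 5723 probe sets were called, 2840 higher and 2883 lower, a count that went to 3748 without day 1 replicate 3 and to 2898 with only the 6 arrays compared, where AT2G37870, COR15A, COR47, COR6.6 and HIS1-3 did not pass. After median centring 3226 were higher and 2472 lower, and with cyclic loess 2886 and 2821.

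From day 2 to day 4 the mitotic kinase genes fell and some of the earlier changes turned back. AUR1 fell 1.84-fold (log2 −0.88 ± 0.11, adjusted p = 7.26e-04), AUR2 fell 1.5-fold (−0.59 ± 0.10, adjusted p = 0.00716) and AGL24 fell 1.60-fold (−0.68 ± 0.09, adjusted p = 0.00118). LTI30 rose 2.17-fold (1.12 ± 0.14, adjusted p = 8.55e-04), RVE6 rose 1.36-fold (0.44 ± 0.08, adjusted p = 0.00583) and AGL42 rose 1.72-fold (0.78 ± 0.14, adjusted p = 0.00737). All 3 cell division genes fell by both counts (median −0.59, adjusted p = 9.55e-05), but MCM7 (−0.39, adjusted p = 0.0357) was lost at 0.0623 with the replicate number as a block and at up to 0.125 without day 0 replicate 2, day 2 replicates 1, 2 or 3 or day 4 replicates 1 or 3. Of 7 ABA-responsive genes 3 rose, and 5 adjusted over the list alone (median 0.47, adjusted p = 4.32e-05). Besides LTI30 these were COR47 (0.75, adjusted p = 0.0397) and HIS1-3 (1.13, adjusted p = 0.0340), and both calls were lost without day 2 replicate 2, day 2 replicate 3 or day 4 replicate 2, at 0.0508 to 0.127. COR47 was lost at up to 0.134 without 7 other pools, day 4 replicate 1 among them. HIS1-3 was lost at 0.0649 with the block, at 0.103 without day 2 replicate 1 and at 0.0988 without day 4 replicate 3. Of 3 clock genes 2 rose, and 3 adjusted over the list alone (median 0.44, adjusted p = 0.00165), but GI (0.50, adjusted p = 0.0242) was lost at 0.0637 to 0.0808 without day 2 replicates 1 or 2 or day 4 replicates 2 or 3. These 3 lists held with an estimated correlation, at adjusted p = 0.0142 for cell division, 0.0277 for ABA-responsive and 0.0262 for clock genes. The xylan list did not pass at adjusted p = 0.0550 (median 0.14) but passed with cyclic loess at 0.0446 and without day 2 replicate 2 at 0.0470. Its highest adjusted p was 0.127, without day 2 replicate 1. The test fry, which does not compare a list with other genes, gave 2.24e-04. The other 5 lists did not pass either (adjusted p = 0.237 to 0.852). AT1G22480 rose 4.27-fold (2.09 ± 0.21, adjusted p = 3.03e-04), AT4G12490 fell 3.76-fold (−1.91 ± 0.20, adjusted p = 3.73e-04) and AT1G52700 fell 2.83-fold (−1.5 ± 0.09, adjusted p = 2.60e-05). The test called 2080 probe sets, 795 higher and 1285 lower, and 311 with only the 6 arrays compared, where AUR2, MCM7, LTI30, COR47, HIS1-3, GI, RVE6, AGL24 and AGL42 did not pass. Without a pool the count was as low as 1151, for day 2 replicate 3, and it moved by over 1.5-fold without day 2 replicate 2 or day 4 replicates 1, 2 or 3 as well.

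From day 4 to day 10 the anthocyanin genes fell, UF3GT by 12.6-fold (log2 −3.65 ± 0.09, adjusted p = 1.81e-10) and DFR by 7.64-fold (−2.93 ± 0.06, adjusted p = 3.43e-11), along with AT5MAT (AT3G29590), an anthocyanin malonyltransferase, by 13.4-fold (−3.74 ± 0.07, adjusted p = 3.27e-11). SWEET13 (AT5G50800), a sucrose transporter, fell 22.3-fold (−4.48 ± 0.14, adjusted p = 1.36e-09). KIN1 fell 6.73-fold (−2.75 ± 0.19, adjusted p = 2.15e-06) and COR15A 4.22-fold (−2.08 ± 0.10, adjusted p = 1.22e-07). GH3.3 fell 3.22-fold (−1.69 ± 0.11, adjusted p = 1.21e-06), and ATC (AT2G27550), a repressor of flowering related to TFL1, fell 11.1-fold (−3.47 ± 0.19, adjusted p = 2.25e-07). Among the rises were AT4G12290 at 7.31-fold (2.87 ± 0.19, adjusted p = 1.48e-06), CDF5 at 3.06-fold (1.61 ± 0.14, adjusted p = 1.42e-05), IRX10 at 1.82-fold (0.86 ± 0.08, adjusted p = 1.49e-05) and FD at 1.68-fold (0.75 ± 0.10, adjusted p = 2.52e-04).

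As lists, ABA-responsive genes fell from day 4 to day 10, with 6 of 7 members lower by both counts (median log2 −0.80, adjusted p = 8.16e-07), and so did cell division genes, with 3 of 3 lower by both counts (median −0.55, adjusted p = 0.00251). Both held with an estimated correlation, at adjusted p = 0.0264 each. The auxin list passed with 2 of 4 members lower by both counts (median −0.48, adjusted p = 0.00856), a call lost at adjusted p = 0.0552 with an estimated correlation. The clock list passed with 1 of 3 members higher, or 2 adjusted over the list alone (median 0.29, adjusted p = 0.0485). That call was lost at adjusted p = 0.0960 with an estimated correlation, at 0.0549 with cyclic loess and at 0.0606 with the replicate number as a block. Without a pool the adjusted p of the clock list ran from 0.0314 to 0.0611. The test fry, which does not compare a list with other genes, gave 1.19e-05. The xylan list did not pass (median 0.31, adjusted p = 0.0926), and neither did the floral list (adjusted p = 0.517, median −0.08, mean 0.19), cambium, gibberellin or lignin (adjusted p = 0.259 to 0.531). The test called 6572 probe sets, 3613 higher and 2959 lower. The balance depended on the scaling, with 2740 higher and 3517 lower after median centring and 2833 and 3528 with cyclic loess, and the count was 3522 with only the 6 arrays compared, where MCM7 and GH3.5 did not pass.

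**Figure D4:**
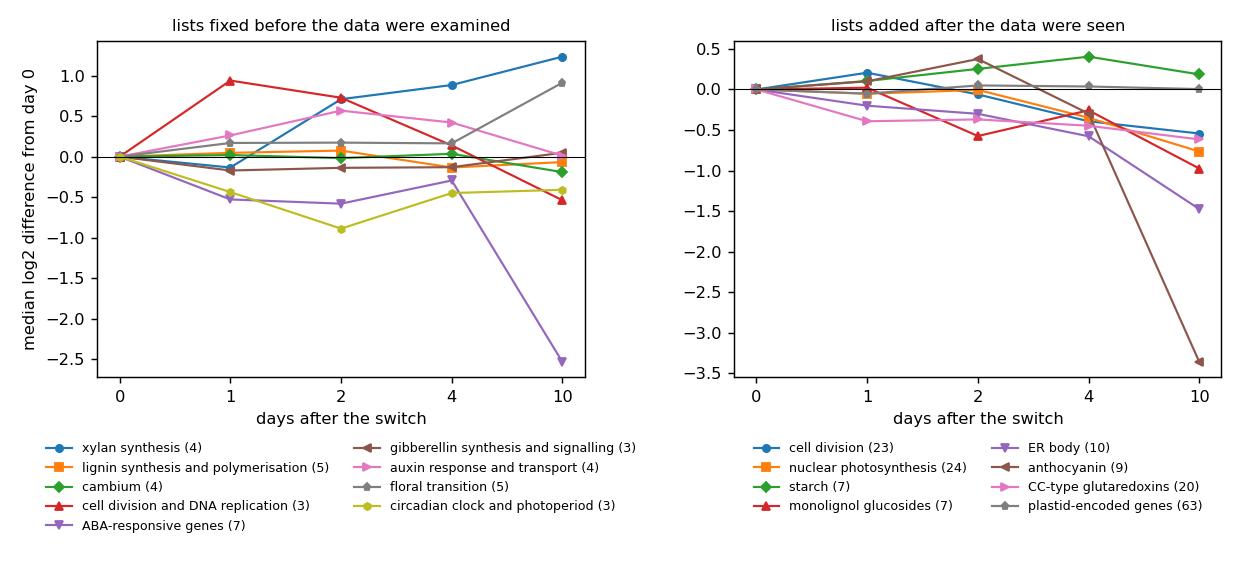
Median log2 difference from day 0 (y axis) of the members of each list on days 0, 1, 2, 4 and 10 (x axis, days evenly spaced), with the number of members in the legend, the lists fixed before the data were examined on the left and those added after the data were seen on the right, on different y ranges. Xylan genes reach 1.23 on day 10, ABA-responsive genes −2.53 and anthocyanin genes −3.36.

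Lists with 1 or 2 members matched by locus tag were not tested as groups. The photosynthesis genes RCA (AT2G39730), Rubisco activase, and LHCB4.1 (AT5G01530), a light-harvesting protein, fell 2.33-fold (log2 −1.22 ± 0.09, adjusted p = 1.17e-06) and 1.63-fold (−0.70 ± 0.10, adjusted p = 1.70e-04) from day 0 to day 10. The root epidermis genes EXPA7 and EXPA18 did not pass in any comparison, and were at −0.003 and 0.25 on day 10 against day 0. BGLU33 (AT2G32860), a glucosidase of the list for ABA synthesis, breakdown and transport, fell 2.08-fold from day 0 to day 2 (−1.06 ± 0.10, adjusted p = 1.75e-05) and rose 1.81-fold from day 2 to day 4 (0.86 ± 0.10, adjusted p = 4.80e-04). AKINBETA1 (AT5G21170), a subunit of the SnRK1 kinase that is induced in the dark, was lower than on day 0 by 1.44-fold on day 1, 1.51-fold on day 2 and 1.67-fold on day 4 (−0.74 ± 0.09, adjusted p = 8.56e-05), and at −0.14 on day 10. OPS (AT3G09070), a phloem regulator, rose 1.5-fold on day 2 (0.58 ± 0.12, adjusted p = 0.00351). The expansin EXPA8 (AT2G40610) fell 1.70-fold by day 10 (−0.76 ± 0.16, adjusted p = 0.00276), and the jasmonate-responsive defensin PDF1.2 (AT5G44420) fell 2.02-fold (−1.02 ± 0.23, adjusted p = 0.00466). The cytokinin response regulators ARR15 (0.59 ± 0.16 on day 2, adjusted p = 0.0214) and ARR16 (−0.69 ± 0.20 on day 4, adjusted p = 0.0246) and the expansin EXPA4 (0.49 ± 0.13 on day 2, adjusted p = 0.0192) passed on 1 day each. Their calls were lost when a pool was left out, at an adjusted p of up to 0.0813, 0.0955 and 0.0773. The flavonoid list holds DFR and UF3GT, given above.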

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

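All alternatives given here were planned, and none reversed the direction of a list or named gene that passed. Which direction had more called probe sets turned with the scaling in every comparison except the step to day 4, where more were lower in each alternative with all 15 pools or with the 6 arrays compared. Leaving out the lowest 25% of probe sets by mean, where signal is closest to background, kept each count of probe sets within 1.5-fold. The count over the 5 days, 15936, was 14205 to 15416 with a pool left out, and 7395 with 1 probe set per gene, where fewer probe sets were tested. With 1 probe set per gene the comparisons with day 0 called 1063, 3441, 4397 and 5431 probe sets on days 1, 2, 4 and 10, and the steps to days 2, 4 and 10 called 2648, 1100 and 3105. With only the 6 arrays compared, which leaves fewer samples for the spread, the counts were 917 on day 1, 5021 on day 2 and 2898, 311 and 3522 for the 3 steps. Without a pool, days 1, 2, 4 and 10 against day 0 gave 1190 to 1836, 5633 to 7790, 7425 to 9896 and 9230 to 11092, and the steps gave 3748 to 5587, 1151 to 2008 and 4810 to 6606. The lowest counts on day 1 and in the first 2 steps came without day 0 replicate 2, day 1 replicate 3 and day 2 replicate 3, and the step to day 4 also moved by over 1.5-fold without day 2 replicate 2 or day 4 replicates 1, 2 or 3. With the replicate number as a block the count over the 5 days was 14877, and the comparisons in the order above gave 1594, 7198, 9374, 10640, 5002, 1641 and 6007. The numbers do not pair the samples: residuals of arrays with the same number correlated at −0.16 to 0.12, and 4 of 15 arrays correlated best with their own number.

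Lists past the test numbered 3 instead of 5 on day 1, 1 instead of 3 on day 4, 1 instead of 2 in the step to day 2 and 2 instead of 4 in the step to day 10 with an estimated correlation. With fry, which does not compare a list with other genes, they numbered 6 on day 4 and 5, 5 and 7 in the steps. Leaving out dim genes gave 1 on day 4 and 1 in the step to day 2, and median centring gave 1 in the step to day 2. Without a pool the ranges were 4 to 6, 4 to 5, 1 to 4 and 3 to 3 on days 1, 2, 4 and 10, and 1 to 2, 3 to 4 and 3 to 4 in the steps. Day 4 went to 1 without day 0 replicate 2, day 1 replicates 2 or 3, day 2 replicate 2, day 4 replicate 3 or day 10 replicates 1, 2 or 3. The step to day 2 went to 1 without day 0 replicate 3, day 1 replicates 2 or 3, day 2 replicate 1, day 4 replicate 2 or day 10 replicates 2 or 3. The floral call on day 1 was lost at adjusted p = 0.0579 without day 1 replicate 3, and the clock calls on day 4 and in the step to day 10 at up to 0.0855 and 0.0611 without a pool. The auxin calls on day 4 and in the step to day 2 were lost at up to 0.0855 and 0.150 without a pool and at 0.0651 and 0.0939 without dim genes. Over all 63 list results, 24 of them calls, cyclic loess ended 1 call and made 2, and the block ended 2. Among 259 calls of named genes, the block ended 14, cyclic loess 1 and the 6 arrays alone 50. Causes other than those given were not tested. Median centring or loess moved the median of all probe sets by less than 0.1 in every comparison.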

Other observations

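The lists of the next 2 paragraphs and the tests of the weighed patterns were chosen only after the results were seen, and the splits of the arrays were planned. Some members were among the genes with the largest changes, so the lists are no independent evidence of direction. AUR1 and AUR2 (cell division), DFR and UF3GT (anthocyanin) and RCA and LHCB4.1 (photosynthesis) are also in the fixed lists above, so they are counted again here. Of 23 cell division genes 9 rose on day 1 against day 0 and 0 fell (median log2 0.21, adjusted p = 1.08e-10). AUR3, an Aurora kinase, rose 1.73-fold (0.79 ± 0.10, adjusted p = 5.22e-04), BUBR1, a spindle checkpoint protein, 1.71-fold (0.77 ± 0.07, adjusted p = 3.44e-05) and TOPII, a topoisomerase, 1.58-fold (0.66 ± 0.08, adjusted p = 2.38e-04). From day 1 to day 2, 11 of the cell division genes fell and 0 rose (median −0.25, adjusted p = 4.47e-10). On day 2 against day 0, 4 rose and 3 fell, and the list did not pass (median −0.06, adjusted p = 0.509). By day 10 against day 0, 18 had fallen and 1, ATMAP65-6, had risen (median −0.54, adjusted p = 3.50e-10), with AUR3 2.02-fold lower (−1.01 ± 0.10, adjusted p = 1.16e-05). All 9 anthocyanin genes fell from day 0 to day 10 (median −3.36, adjusted p = 4.99e-16), although 5 had risen on day 2 (median 0.38, adjusted p = 7.00e-04). The day 2 call was lost at adjusted p = 0.144 with an estimated correlation. Of 24 nuclear photosynthesis genes 16 fell and 2 rose by day 10 (median −0.77, adjusted p = 1.02e-09), with PRK, phosphoribulokinase of the Calvin cycle, 4.86-fold lower (−2.28 ± 0.15, adjusted p = 2.86e-07). Of 63 plastid-encoded genes 10 rose and 12 fell by day 10, and the list did not pass (median 0.01, adjusted p = 0.737).

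Of 10 genes of the ER body, a compartment that stores glucosidases, 9 fell by day 10 (median −1.48, adjusted p = 1.55e-11), with NAI2, which shapes it, 2.80-fold lower (−1.48 ± 0.09, adjusted p = 9.76e-08) and the glucosidase PYK10 1.97-fold lower (−0.98 ± 0.06, adjusted p = 2.18e-07). Of 7 genes that attach or remove glucose on monolignols 4 fell and 1 rose (median −0.98, adjusted p = 0.0138), with BGLU47 8.77-fold lower (−3.13 ± 0.09, adjusted p = 6.25e-10). Of 7 starch genes 4 rose and 1 fell on day 4 (median 0.41, adjusted p = 0.00412), with the ADP-glucose pyrophosphorylase subunits APL4 3.89-fold higher (1.96 ± 0.10, adjusted p = 1.81e-07) and APL3 3.21-fold higher (1.69 ± 0.13, adjusted p = 3.04e-06). The starch call was lost at adjusted p = 0.115 with an estimated correlation. Of 57 families by symbol stem, the jacalin-like JAL family had all 5 members lower on day 10 than on day 0 (median −1.54, adjusted p = 2.81e-06), and these 5 are also in the ER body list, so this is no separate result. All 8 autophagy genes of the ATG family rose by day 10 (median 0.59, adjusted p = 1.06e-04), a list call lost at adjusted p = 0.262 with an estimated correlation. With an estimated correlation the cell division calls on days 1 and 10 held at adjusted p = 0.00562 and 0.0027. That of the step to day 2 held at 0.00704. Day 10 calls of anthocyanin and ER body genes held at 0.0027 and 0.00214. Those of photosynthesis, monolignol glucoside and JAL genes held at 0.0325, 0.033 and 0.0313.

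ABA-responsive and clock genes were lower 1 day after the switch than before it, and a response to the switch may account for this. No plants kept in short days were sampled after day 0, so plant age cannot be told apart from the switch. Against a difference in scale left between the arrays, the ABA-responsive median was −0.51 with cyclic loess. The normalization already in the deposited values cannot be tested this way. Against 1 deviating pool, that median was closest to 0 at −0.34 when each pool was left out in turn, with an adjusted p of at most 2.07e-05 in those fits. The hour of harvest cannot be told apart from the switch, because GI, whose transcript cycles daily, fell by 1.80 and the labels give no hour. The response itself was not tested apart from the hour or from plant age.

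Anthocyanin genes fell from day 4 to day 10 by a median of −3.14 on the log2 scale, and the age of the tissue or its longer time in long days may lie behind it. The median was −3.14 with cyclic loess and at most −3.08 with each pool left out in turn, with all 9 genes still lower. This argues against a difference in scale left between the arrays and against 1 deviating pool. The normalization already in the deposited values was not tested. A smaller share of green tissue in the later pools would lower nuclear photosynthesis genes as well, and these had a median of −0.33, with quartiles of −0.69 and 0.02. They thus fell much less than the anthocyanin genes, which argues against it unless the remaining tissue holds photosynthesis transcripts of its own, and as no value measures those, it cannot be told apart. Both days lie after the switch, so day length is the same, while age and time in long days increase together and were not tested separately. The labels give no hour of harvest, so the hour cannot be told apart here either.

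CC-type glutaredoxins were lower on day 4 than on day 0 in 10 of 20 members, while 4 rose (median −0.45, adjusted p = 0.0190), a list call lost at adjusted p = 0.115 with an estimated correlation. Against day 0, 7 fell and 1 rose on day 1, and 11 fell and 3 rose on day 10. These 2 list calls held with an estimated correlation, at adjusted p = 0.0314 and 0.033. On day 2, 9 fell and 4 rose, and the list call was lost at 0.144. A response to the switch is a candidate explanation, and it was not tested apart from plant age or the hour of harvest. With cyclic loess the 10 members lower on day 4 were still lower, and after median centring 8 were lower and 5 higher. Most of the falls thus did not depend on a difference in scale left between the arrays. The normalization already in the deposited values was not tested. Among the tandem copies AT4G15660 to AT4G15700 all 5 fell, by −3.37 to −1.75, and outside them 5 of 15 fell, which are AT3G62930 and AT3G62950, neighbours of each other, and ROXY2, AT5G18600 and AT1G03020. Probe sets shared by tandem or neighbouring copies cannot be told apart from separate falls of such copies, because no probe sequences were used here.

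For the 5 days, 1 of 100 drawn splits of the 15 arrays gave as many probe sets, the real one with 15936, and the highest other gave 3305. A random assignment of arrays to days is thus unlikely to give as many. The splits cannot separate the days from anything else that changed with them. For the pairs of days 10 splits are too few for a share under 0.05. The real and highest other counts were 1874 and 4 for day 1, 7832 and 0 for day 2, 9869 and 6 for day 4 and 11066 and 0 for day 10, each against day 0. For the steps they were 5723 and 1 to day 2, 2080 and 0 to day 4 and 6572 and 8 to day 10. In each of these, 1 of 10 splits, the real one, was as large. For lists past the test, real and highest other counts were 5 and 2, 4 and 1, 3 and 1 and 3 and 1 on days 1, 2, 4 and 10, and 2 and 1, 3 and 4, and 4 and 1 in the steps, where 3 of 10 splits were as large for the step to day 4 and 1 of 10 elsewhere.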
